A study of Mus musculus with 10 samples.

How the data were processed

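RNA was measured in mouse embryonic fibroblasts (MEFs), primary connective tissue cells grown from C57BL/6 embryos at embryonic day 14 and used at passage 3. Per the labels, 5 libraries came from male and 5 from female cells, total RNA was depleted of ribosomal RNA, and strand-specific libraries were read on a NextSeq 500. Replicate numbers were taken from the sample titles. The labels do not say whether the libraries of a sex came from separate embryos or cultures, so p-values measure only the spread between these samples, which may be technical.

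The authors deposited 1 table of 52550 genes with whole-number read counts for each library, not normalized, per the file headers. The headers separate unique reads from total reads, and gene reads (exons with introns) from exon reads, intron reads and reads across exon junctions. The aligner, the counting rules and the trimming are not given in the sources used here. The genome build is mm10, per the submitters' processing notes. Starts in the deposited table count from 0 and were converted to count from 1. Of the gene identifiers, 52403 were in GENCODE release M21, and 95.2% of those had the same start and end there. The authors also deposited a p-value, a false discovery rate and a signed fold for each gene from their own test of males against females, which the file headers name an EDGE test with tagwise dispersions. A further 90 columns of values per library were not used.

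Unique gene reads were chosen before the data were examined, as were the test, the gene lists and the alternatives, except for those named here and in the closing section as added later. Unique gene reads came to between 30662616 and 45859721 per library, and total gene reads to between 36295813 and 54643418. With edgeR 4.0.16 in R 4.3.3, genes were kept by filterByExpr with its minimum count of 10, which left 16602 genes. Libraries were scaled by TMM factors, and a robust quasi-likelihood fit with sex as the only term was tested on both sides. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. Fold changes are log2, female minus male, from that fit. Their standard errors were taken as the size of the log2 fold change divided by the square root of the F statistic. Levels are CPM with TMM scaling, given as mean ± SD. A gene with no read in a group was compared against a floor of 3 reads over that group, which covers counting error only, since reads without molecular identifiers are not independent molecules.

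Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, for lists with at least 5 tested members, and again with the correlation estimated from the data. There were 35 lists. The Y-linked list and the list of X genes known to escape X inactivation follow from the karyotype and were left out of the adjustment over lists, which covered 32 lists. Beside the adjustment over all genes, each list's members were also adjusted over the list alone. The named genes are the measured members of the Y-linked list, the escape list and the list of X homologs of Y genes. To these the rule adds up to 10 autosomal calls per direction with a mean of at least 1 CPM, no overlap between the sexes and no predicted-model symbol, and up to 5 X calls per direction outside the escape list. It also adds up to 4 members of each described list with the smallest p, and the passing and most abundant members of the lists for other cell types. Any other gene named was chosen after its values were seen.

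The counts test was run on simulated data made from the real means, the library sizes and edgeR's dispersion estimates, with 200 changed genes among 16520. It recovered 12% of genes changed 1.25-fold, 74% of those changed 1.5-fold, 96% of those changed 2-fold and 100% of those changed 4-fold, and 6% of its calls were unchanged genes. The changed genes lay off the X and Y and had a mean of at least 1 CPM, so recovery at lower levels was not tested. Counts were drawn for each gene on its own, with no structure shared between genes, so these rates may not hold for the real libraries. The alternatives were size factors or upper quartile factors in place of TMM, no filter or a stricter filter of at least 1 CPM in 5 libraries, DESeq2 1.42.0, limma-voom, and the replicate number as a block. Others were 1 surrogate variable from sva 3.50.0, leaving out each library in turn, total gene reads, and adjustment over autosomal genes alone. Unique exon reads, and the counts without Gm26917 and CT010467.1, which hold ribosomal RNA reads, were added after the data were seen. Other values were computed in Python 3 with scipy.

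Between libraries of a sex, counts differed by far more than sampling noise, so no library was taken for a second copy of another. The share of unique reads on Gm26917 was 9.08% ± 0.97 in females and 8.64% ± 0.43 in males (SD, n = 5; two-sided exact permutation p = 0.397). None of the 13 library measures compared between the sexes, such as depth, intron share and mitochondrial share, had a two-sided exact permutation p below 0.143.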

Results

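The data set asks which genes differ in expression between male and female MEFs. It holds 10 libraries, 5 per sex, with 39664400 ± 3924410 unique gene reads in females and 36113700 ± 4179290 in males (SD, n = 5). Of 16602 tested genes, 16017 were autosomal, 549 lay on the X and 9 on the Y. The quasi-likelihood test of edgeR called 15 genes, 7 higher in females and 8 higher in males. All 7 called higher in females were X-linked, and the 8 higher in males comprised 5 Y-linked and 3 autosomal genes.

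The male libraries carried transcripts of Y-linked genes that were near absent from female libraries. Ddx3y, an RNA helicase gene, was at 59.5 ± 5.30 CPM in males and 0.241 ± 0.178 in females (SD, n = 5). Uty and Kdm5d, which belong to histone demethylase families, were at 45.4 ± 8.48 and 21.8 ± 1.23 CPM in males and at 0.292 ± 0.067 and 0.213 ± 0.091 in females. Eif2s3y, a subunit gene of a translation initiation factor, was at 28.6 ± 6.48 CPM in males and 0.056 ± 0.022 in females. These 4 were called, with log2 fold changes between -8.92 (Eif2s3y) and -6.66 (Kdm5d). Kdm5d had the smallest adjusted p of the 15 calls, 1.38e-12. Usp9y, the other tested member of the Y-linked list, was not called, with 58 reads summed over the males and 62 over the females. Sry, the testis-determining gene, had 0 reads in all 10 libraries, fewer than the 3 that a count of 0 allows. Gm29650, a noncoding Y gene at 1048393 to 1049134, had between 12 and 24 reads in each male library and 0 in each female library. It was therefore at least 34.4-fold higher in males against a floor of 3 reads over the female group, and was chosen after its values were seen. It was not called with DESeq2. The stricter filter removed it, so it was not tested there. All its reads were counted as intron reads, although its exon length of 742 bases covers its whole span. With exon reads it was not tested either.

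Female libraries expressed Xist, the noncoding RNA that coats the inactive X, at 21.3 ± 3.23 CPM, while male libraries had 0.022 ± 0.024 (SD, n = 5). A further 6 X genes rose in females by far less. Eif2s3x was 1.61-fold higher (206 ± 9.41 against 128 ± 9.22 CPM), Kdm5c 1.44-fold (162 ± 6.16 against 112 ± 7.74), Kdm6a 1.39-fold (45.7 ± 1.67 against 32.8 ± 2.29) and Ddx3x 1.24-fold (390 ± 14.6 against 315 ± 8.70). Pbdc1 was 1.42-fold higher and its neighbour 5530601H04Rik, a noncoding transcript on the opposite strand, 1.61-fold. Eif2s3x, Kdm5c, Kdm6a and Ddx3x are the X homologs of the Y genes called above. All 7 genes belong to the list of X genes known to escape inactivation. Of that list's 14 tested members, 7 were called over all genes and 8 passed when adjusted over the list alone, the eighth being Ftx.

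The log2 fold change of Xist was 9.72 ± 0.26 (SE), with adjusted p = 2.78e-12. For Eif2s3x it was 0.68 ± 0.06, for Kdm5c 0.53 ± 0.06 and for Kdm6a 0.48 ± 0.06, with adjusted p of 1.68e-05, 0.000212 and 0.00158 in the same edgeR test. Only 5.55% of the reads on Xist, which lies at 103460375 to 103483217 of the X inside the span of Tsix, counted as unique. With total gene reads, the log2 fold change of Xist was 10.71. For Eif2s3x the unique share was 59.4%. Ddx3x lost its call without male replicate 2 (adjusted p = 0.055), male replicate 5 (0.0641), female replicate 1 (0.0866) or female replicate 4 (0.0812). The call on 5530601H04Rik was lost without female replicate 3 (adjusted p = 0.0549) and with exon reads (0.382).

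Not every escape gene or X homolog was called. Utp14a, Firre, Mid1, 1810030O07Rik, Car5b and Jpx had log2 fold changes from -0.33 (Car5b) to 0.18 (Jpx). Usp9x, Uba1 and Zfx, X homologs of further Y genes, had log2 fold changes of -0.04, -0.02 and 0.09. The list of X homologs was higher in females as a group, with 4 of 7 members called and a camera adjusted p of 4.60e-11. Its adjusted p = 0.00628 with an estimated correlation. Its 4 called members belong to the escape list too.

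**Figure D1:**
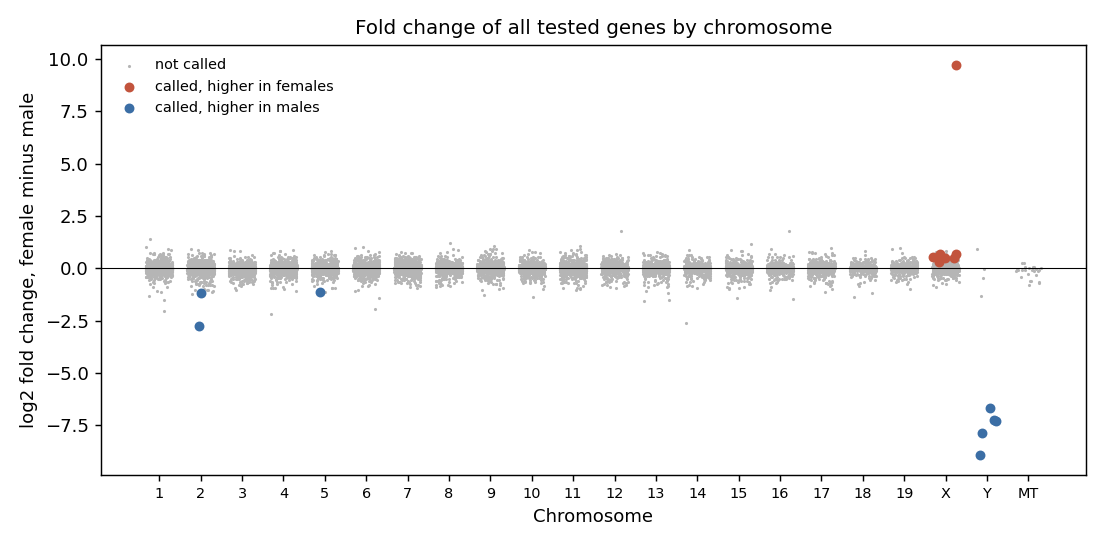
Log2 fold change (female minus male) of each tested gene, by chromosome, with 1 point per gene; coloured points are the 15 called genes. The calls lie on the X, on the Y, and at 3 autosomal genes on chromosomes 2 and 5.

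**Figure D2:**
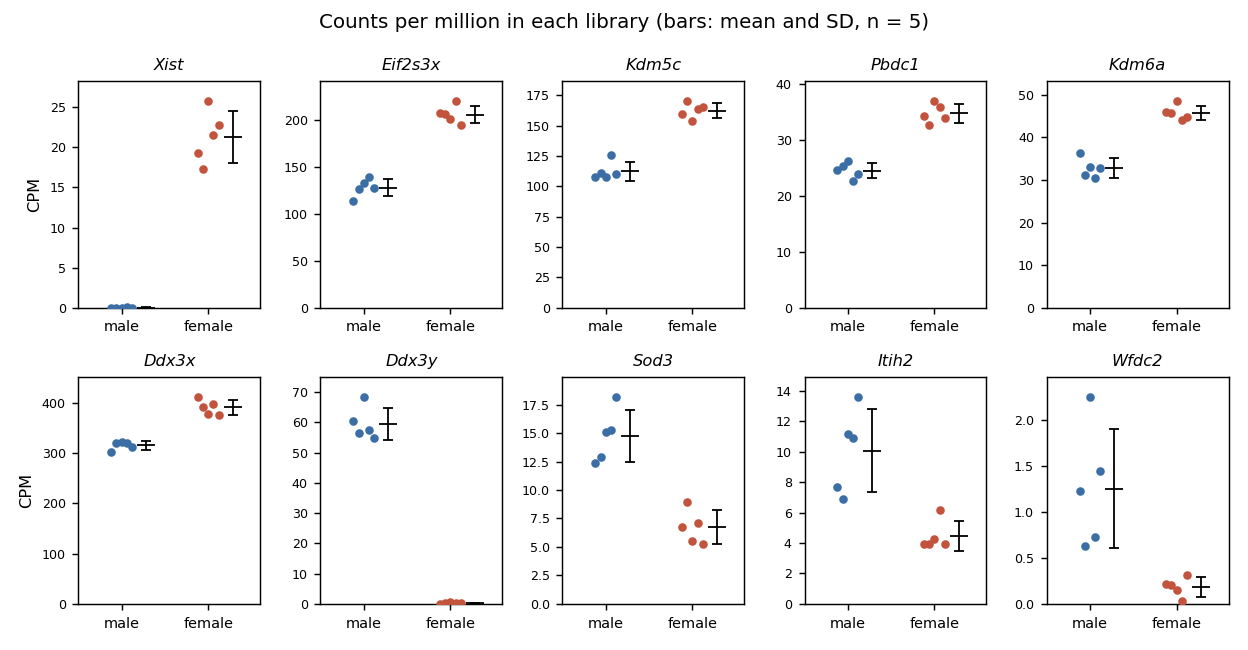
CPM per library of 10 called genes in male and female MEFs, on linear axes that start at 0; horizontal marks and bars are the mean and SD (n = 5). The males and females do not overlap for any of the genes shown.

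The rest of the X was at nearly the same level in both sexes. Across the 535 tested X genes outside the escape list, the median log2 fold change was -0.01, with an interquartile range from -0.10 to 0.06. None of them was among the 15 calls, while 33 had an unadjusted p under 0.05, 14 of them higher in females and 19 in males. Nhsl2 was called without male replicate 1. Gm21887 was called by DESeq2, and by edgeR with no filter, with the replicate block and with 1 surrogate variable, but only 3.36% of its reads were unique. The camera test of these genes against the rest gave p = 0.248, and p = 0.425 with an estimated correlation. The median X level relative to autosomal genes was -0.01 ± 0.04 in females and 0.01 ± 0.02 in males on the log2 scale (SD, n = 5; two-sided exact permutation p = 0.5).

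Among autosomal genes, Sod3, which encodes the extracellular superoxide dismutase, was lower in females, at 6.73 ± 1.47 CPM against 14.8 ± 2.29 in males (SD, n = 5). Itih2, a heavy chain of the inter-alpha-trypsin inhibitor that binds hyaluronan, was at 4.44 ± 0.99 CPM in females and 10.1 ± 2.73 in males. Wfdc2, a secreted protease inhibitor family gene, was at 0.182 ± 0.105 CPM in females and 1.25 ± 0.65 in males. Wfdc2 had a mean below 1 CPM and was chosen after its values were seen. The log2 fold changes were -1.13 ± 0.15 for Sod3, -1.18 ± 0.19 for Itih2 and -2.75 ± 0.44 for Wfdc2 (SE), with adjusted p of 0.00212, 0.031 and 0.0257 by edgeR. Each of the 5 male libraries was above each of the 5 female libraries for all 3 genes. Sod3 lies at 52363791 to 52371418 of chromosome 5, Itih2 at 10094593 to 10131396 and Wfdc2 at 164562413 to 164568510 of chromosome 2.

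None of the 15 calls was an autosomal gene higher in females. At an unadjusted p under 0.05 there were 318 autosomal genes higher in females and 552 higher in males, 870 in all. DESeq2 called 3 autosomal genes higher in females and 57 higher in males, and limma-voom called 1 in males and none in females. In the simulated data 14% of DESeq2's calls were unchanged genes, against 6% for edgeR. Those data were drawn with edgeR's own dispersion estimates, so they do not settle whether DESeq2's further calls are false. Sod3 was called in each of the 10 fits that left out a library, with log2 fold changes from -1.26 to -1.05 and adjusted p up to 0.0137. Itih2 lost its call in 7 of them, without male replicate 3 (adjusted p = 0.119), 4 (0.0938) or 5 (0.0563) or female replicate 1 (0.144), 2 (0.11), 3 (0.134) or 5 (0.162). Wfdc2 lost it in 5, without male replicate 3 (0.0588) or 5 (0.0791) or female replicate 1 (0.101), 2 (0.1) or 3 (0.134). Leaving out male replicate 1 raised the autosomal calls to 8 in females and 15 in males. The autosomal genes whose libraries of the sexes did not overlap were 145, or 0.905%, where chance gives 0.794%. The first principal component of the 1000 most variable autosomal genes held 17.6% of the variance and did not separate the sexes (two-sided exact permutation p = 0.0952, adjusted over 3 components 0.202).

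The authors' deposited table calls more genes. It lists 82 genes with a false discovery rate under 0.05, 20 higher in females and 62 in males, of which 67 are autosomal (11 and 56), and it contains the 15 genes called here. Its male-higher genes include the cartilage genes Col10a1, Hapln1 and Col2a1, the 5' Hox gene Hoxd13 and Angptl7, with signed folds in the authors' deposited table of -2.52, -2.83, -2.64, -1.98 and -3.80. Pgr, the progesterone receptor gene, has a fold of 2.10 in females there. None of these 6 was among the 15 calls. DESeq2 called Col10a1, Hapln1, Angptl7 and Pgr. With edgeR, Col10a1 and Hapln1 were called with no filter, with the replicate block and without male replicate 1. Col10a1 was also called with total reads, Hapln1 without female replicate 2 and Pgr without female replicate 5.

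Gene lists fixed beforehand showed small shifts that rested on the preset correlation. Ribosomal protein genes were higher in females in 29 of 32 members, with a median log2 fold change of 0.10, and no member passed over all genes or adjusted over the list alone. Rps18, Rpl11 and Rpl14 had log2 fold changes of 0.20, 0.20 and 0.17, with unique shares of only 14.3%, 17.1% and 15.9%. With total reads these were 0.13, 0.20 and 0.08. The camera adjusted p was 5.69e-08, and the adjusted p = 0.566 with an estimated correlation. Replication-dependent histone genes, such as Hist1h1c and Hist1h1e, were positive in 17 of 18 members (median 0.15, adjusted p = 0.000546, and adjusted p = 0.84 with an estimated correlation). Cell cycle genes, Birc5 and Cdk1 among them, were positive in 28 of 32 (median 0.07, adjusted p = 0.0271, and adjusted p = 0.84 with an estimated correlation). Cholesterol synthesis genes were positive in 23 of 23 (median 0.14, adjusted p = 0.00369, and adjusted p = 0.84 with an estimated correlation). Ribosomal protein genes were called in each fit that left out a library. The histone list lost its call without male replicate 1 (adjusted p = 0.0972) or female replicate 5 (0.219), and the cell cycle list without male replicate 1 (0.676) or 2 (0.206) or female replicate 4 (0.19) or 5 (0.946, with the direction turned). The cholesterol list lost its call without male replicate 3 (0.225) or 5 (0.122) or female replicate 1 (0.205) or 2 (0.438), and with 1 surrogate variable, where its direction turned (0.799). In the other direction, the list of xenobiotic and Nrf2 target genes was negative in 14 of 19 members (median -0.08, adjusted p = 0.00856, and adjusted p = 0.456 with an estimated correlation). Ahr, the aryl hydrocarbon receptor gene, passed when adjusted over the list alone (0.0139) at 11.4 ± 1.30 CPM in females and 15.3 ± 1.74 in males (SD, n = 5). Ahrr, Txnrd1 and Hmox1 had log2 fold changes of -0.78, -0.24 and -0.33 and did not pass. This list lost its call without female replicate 5 (adjusted p = 0.111).

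Of the marker lists for other cell types, macrophage, cartilage and neural markers were called at the preset correlation, and none of them with an estimated one. Macrophage markers were positive in 15 of 15 tested genes (median 0.19, adjusted p = 0.0128, and adjusted p = 0.84 with an estimated correlation), with Lyz2 the most abundant and Adgre1 and Cd68 at log2 fold changes of 0.36 and 0.38. Cartilage and bone markers were negative in 9 of 12 (median -0.25, adjusted p = 0.0196, and adjusted p = 0.269 with an estimated correlation). Sox6, a transcription factor of cartilage differentiation, passed when adjusted over the list alone (0.011), at 11.1 ± 2.39 CPM in females and 18.2 ± 3.82 in males. Sox9, from the same list, went the other way at a log2 fold change of 0.15, and Spp1 was its most abundant gene. Neural and glial markers were negative in 9 of 13 (median -0.19, adjusted p = 0.0281, and adjusted p = 0.456 with an estimated correlation). Nes, the most abundant, went the other way at a log2 fold change of 0.08, while S100b was at -0.86, or -0.51 with total reads. The macrophage list lost its call without male replicate 2 (adjusted p = 0.0968) or female replicate 5 (0.596), and the cartilage list without female replicate 4 (0.127). The neural list lost it without male replicate 2 (0.0968) or 4 (0.15) or female replicate 2 (0.0781), 4 (0.0688) or 5 (0.0753), and with no filter (0.143) or the stricter one (0.141). Of the epithelial markers, Msln and Krt7 passed when adjusted over the list alone with log2 fold changes of -0.77 and -0.89, while Krt8 and Krt18 were at 0.84 and 0.29 and Krt19 was the most abundant. The most abundant endothelial, muscle and gonadal markers were Flt1, Des and Fst, and these lists were not called. Only 2 genes of the liver and blood list were tested, Alb among them, so that list had no camera test.

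Of the Hox genes, 22 of 33 tested had a positive log2 fold change and 11 a negative one. None was among the 15 calls. Hoxa13, Hoxd11 and Hoxd13 passed when adjusted over the list alone, with log2 fold changes of -0.65, -0.75 and -0.99, whereas Hoxb9, the most abundant, was at 0.35. The list median was 0.19 (camera adjusted p = 0.0865, and 0.456 with an estimated correlation). Among genes of hormone action, Pgr and Fkbp5 passed when adjusted over the list alone, at log2 fold changes of 1.07 and 0.31. Adamts5 and Timp2 of the matrix remodelling list (-0.25 and -0.25) and Ankrd37 of the glycolysis and hypoxia list (-0.89) also passed over their lists alone. Thbs1, the most abundant of the collagen and matrix genes, and Fbln5 and Mfap5 did not pass, nor did the imprinted genes H19, Igf2 and Plagl1, at 0.38, 0.35 and -0.42. Including the Hox, hormone and other uncalled lists just described, 23 lists were not called, with adjusted p from 0.0793 to 0.891. The rest of these were lists of X inactivation factors, contractile genes, limb patterning, interferon response, inflammation, p53 and senescence, fatty acid and adipogenic genes, oxidative phosphorylation, mitochondrially encoded genes, the unfolded protein response, heat shock, immediate early genes and growth factor signalling. Some of the 23 were called in a part of the 20 edgeR fits: matrix remodelling in 5, interferon response and imprinted genes in 4 each, the unfolded protein response in 3, and a few more in 1 or 2. The smallest adjusted p came without female replicate 5, at 3.42e-06 for interferon response and 0.000101 for the unfolded protein response, both higher in females. For matrix remodelling it was 0.00307 without female replicate 2, lower in females. With all libraries and an estimated correlation, the adjusted p was 0.84 for each of these 3 lists and 0.58 for imprinted genes.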

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

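In 182 groups of 5 libraries (78 genes and 13 library measures in each sex), 9 held a library far from the other 4, by Dixon's test at the 95% level. Chance gives about 1 in 20 groups, or 9.1. In male replicate 4, Kdm5c was at 123 CPM against 109 to 112 in the other males. In male replicate 3, Krt18 was at 6.13 CPM against 8.22 to 8.75. In female replicate 5, Hist1h1e was at 108 CPM against 66.6 to 78.3, Flt1 at 119 against 71.2 to 80.4, and Erg at 2.60 against 1.39 to 1.56. In female replicate 1, Ahrr was at 3.86 CPM against 5.93 to 6.53, and in female replicate 3, Msx2 was at 6.56 CPM against 5.02 to 5.47. Female replicate 3, the deepest library, had 17534 genes with at least 10 reads against 16579 to 16804 in the other females, and 16.3% of its reads on its 10 most abundant genes against 18.4% or more in the others. These CPM values are without TMM scaling, and no explanation was tested for them.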

How the results depend on the processing

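Unique exon reads and the counts without the 2 ribosomal RNA genes were chosen after seeing the data. The 15 calls held with size factors, upper quartile factors, total reads and the counts without the 2 ribosomal RNA genes, and total reads added Col10a1. The stricter filter left 13 calls, since it removed Gm29650 and Wfdc2 from the test, and limma-voom left 13, without Wfdc2 (adjusted p = 0.126) and Itih2 (0.0649). Without a filter, 22 genes were called higher in males, 17 of them autosomal. DESeq2 called 11 in females and 61 in males, with 3 and 57 autosomal. Autosomal calls in males numbered 1 with limma-voom, 5 with 1 surrogate variable, 6 with exon reads and 1 (Sod3) when adjusted over autosomal genes alone. The cause of these changes was not tested. Leaving out each library in turn gave 6 to 16 calls in females and 6 to 20 in males, with 0 to 8 and 1 to 15 autosomal, and 6 to 13 lists; the highest gene counts came without male replicate 1. Of the 15 genes, 11 were called in each of these fits. The X median lay between -0.01 and 0.00 in them. The number of called lists fell to 1 with an estimated correlation in camera. Of 1626 values of 78 named genes under alternatives, 1579 kept their side of the threshold, 20 lost the call and 27 gained it. Direction turned in 21 of the 1579, all uncalled, and in no called value. At this depth the simulated test recovered 12% of 1.25-fold changes, so small differences were mostly not detectable.

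Same-numbered libraries of the sexes deviated together with correlations of 0.0823, 0.0735, 0.139, 0.0425 and 0.241. All were positive but weak, so whether the replicate numbers pair the libraries stays open, and the main fit did not pair them. Only replicates 3 and 5 correlated best with their own number. With the replicate number as a block, 8 genes were called in females and 35 in males, 30 of the latter autosomal (3 in the main fit), and 13 lists.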

Other observations

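The splits of the libraries, the limb and epithelial tests, the chi-square test of Y genes and the exon share of Eif2s3y were chosen after the results were seen. The exon share of all the Y reads and the unique share of nested genes were not.

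The Hox genes were also grouped by position in their clusters, a grouping chosen after the values were seen, and the difference between the groups was not tested. Paralog groups 1 to 9 were positive in 18 of 22 tested genes, with a median log2 fold change of 0.29, while groups 10 to 13 were negative in 7 of 11, with a median of -0.36. Of 11 genes of distal limb segments, Hox genes among them, 8 were lower in females, with a median log2 fold change of -0.36. Of 10 proximal limb genes, 5 were lower, with a median of 0.03.

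Erdr1, which the table places on the Y, had 41.4, 52.1, 158, 154 and 119 CPM in female replicates 1 to 5 and between 35.8 and 73.9 in males (two-sided exact permutation p = 0.127, without TMM scaling). Gm21887, on the X and with few unique reads, had 7.27 ± 2.14 CPM in females and 4.13 ± 0.48 in males (SD, n = 5, adjusted p = 0.208 by edgeR). In female replicates 1 to 5 it had 5.12, 5.26, 7.96, 10.28 and 7.73 CPM. Both genes were thus highest in female replicates 3, 4 and 5, so they are not shown to be separate observations.

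Most autosomal genes near the threshold were higher in males, 84 of the 100 with the smallest p. A candidate explanation is more cells of distal limb origin in the male cultures: a score of 11 distal against 10 proximal limb genes differed by -0.30 ± 0.12 (female minus male, log2, SE; two-sided exact permutation p = 0.0397), which is what that explanation needs. Without its 4 Hox genes and Msx2 the difference was -0.27 ± 0.10 (p = 0.0317, same exact test), but some of the other genes belong to a list whose test had been seen, and male replicate 1 scored -0.22 with all the genes, among the females. More epithelial or mesothelial cells in the males stay open, since 7 of 14 epithelial genes had a negative fold and 7 a positive one. Sex itself stays open, and chance could not be excluded: 6 of 100 splits of the 10 libraries gave as many autosomal calls, 3 in the real split and up to 122 in another.

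For all genes, 5 of 100 splits gave as many calls as the real 15, with 130 the highest of the others, so the number of calls alone does not exclude chance. For autosomal genes with an unadjusted p under 0.05, 32 of 100 splits gave as many as the real 870, up to 2697. For calls off the autosomes, 1 of 100, the real split, gave 12, with 8 the highest other, which excludes chance for their number but not for each gene. Since Y-linked and escape genes follow from the karyotype, this count adds little beyond the sex of the libraries. The split of male replicates 1, 2 and 4 with female replicates 1 and 2 against the rest called 130 genes, and that of male replicates 1, 3 and 5 with female replicates 3 and 5 called 45. Both kept same-numbered libraries of the sexes on the same side, except replicate 4 in the first split and replicate 1 in the second. That of male replicates 1 and 2 with female replicates 1, 2 and 4 called 20 genes, and parted only replicate 4. That of male replicates 1 and 5 with female replicates 1, 2 and 5 called 3, and parted only replicate 2. Others that parted only 1 replicate number called 0 genes, such as male replicates 1, 2 and 3 with female replicates 1 and 3. Male replicate 1 with female replicates 1, 2, 3 and 5 called 19 genes, and parted replicates 2, 3 and 5. Whether such splits follow the replicate numbers, another structure of the samples or chance was not tested. For the called lists, 49 of 100 splits gave as many as the real 9, up to 15, and for the size of the X median, 56 of 100 gave as much as 0.0121, up to 0.0395; neither excludes chance.

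The Y genes Ddx3y, Eif2s3y, Kdm5d and Uty had 50, 11, 42 and 58 reads over all female libraries. Reads assigned to the wrong library of a pool would give each gene the same female to male ratio, but these were 0.466%, 0.213%, 1.06% and 0.706% (chi-square p = 4.25e-07 on summed reads, counting error only). Reads of X homologs would lie mostly in exons, but the exon share was 19.9% in females, 32 exon and 129 intron reads, against 72.0% in males (Fisher's exact p = 1.55e-42). Neither can then be the whole source, but Eif2s3y had 11 exon and 0 intron reads in females (Fisher's exact p = 0.234 against males), so reads of its X homolog stay open for it. Some other Y genes had reads at a similar level in both sexes. Usp9y had 62 female and 58 male reads, 96.7% of them counted as intron reads. Zfy1 had 19 female and 16 male reads, and Zfy2 had 17 and 22. Whether intronic reads of similar sequence elsewhere explain the female reads was not tested.

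The low unique share of Xist may come from overlapping gene models. Genes wholly inside a gene on the other strand had a median unique share of 31.4% (255 genes), against 99.8% for 7872 genes with no overlap. For genes inside a gene on the same strand it was 26.05% (131 genes), so a low share was not particular to overlap on the other strand. Tsix had between 14 and 29 total reads in each female library against 12905 to 20909 for Xist, so total reads were kept apart by strand. Whether reads placed at several sites add to it was not tested.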
